A study of Mus musculus with 6 samples.

How the data were processed

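The series holds RNA sequencing of primary mouse bone marrow stromal cells, the adherent marrow cells that can form osteoblasts and adipocytes. Per the labels, the cells were kept for 2 days under osteogenic induction. Per the series description, the donor mice were 8 weeks old and carried a floxed Rras2 gene with or without a Prx1 construct. The Prx1 promoter is used to drive the deletion of floxed genes in limb mesenchyme. There were 3 libraries labelled as floxed controls, called FF here, and 3 labelled as conditional knockout, called cKO here. Per the labels' protocols, libraries were made from total RNA with a stranded mRNA kit. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the authors' test are not given in the sources used here.

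The deposited table held 12830 genes, with gene counts for each of the 6 libraries as the authors counted them, not normalized. Per the file headers, the table also gave an FPKM value for each gene and library, which scales the count by gene length and library size. The FPKM values were used only to check that columns belonged together. Per the file headers, the authors' table gave a log2 fold change, a p-value and an adjusted p-value for each gene. The deposited adjusted p-values differed from a Benjamini-Hochberg adjustment over the table by at most 2.73e-15. A default DESeq2 test run here gave log2 fold changes within 0.000109 of the deposited ones and called the same 848 genes at an adjusted p below 0.05. The authors' direction column marked genes with an unadjusted p below 0.05 and a fold change above 1.5, with 0 exceptions. The lowest mean count of any gene was 22.3 per library, so genes of lower count are not analysed here.

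Summed over the genes of the table, FF replicates 1, 2 and 3 held 35037413, 37561452 and 31934714 counts. The cKO replicates held 35071025, 34612725 and 36403427 counts. These sums cover the listed genes and are not the full sequencing depth. The median count per gene and library was 1075. Of the row identifiers, 12638 were Ensembl mouse gene identifiers and 191 were MSTRG identifiers, without an annotated gene name. GENCODE M21, an annotation of the same build, matched 12611 of them and gave the coordinates and gene types used here.

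Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, the quasi-likelihood F test with robust estimation and no covariates. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all tested genes were called. The filter removed 0 genes. Values per library are CPM, counts scaled to a common library size with TMM factors, given as mean ± SD over 3 libraries. The standard error of a log2 fold change was the fitted coefficient divided by the square root of F. On simulated counts for 12830 genes in this comparison, the test recovered 34% of genes changed 1.3-fold, 68% at 1.5-fold, 86% at 2-fold and 96% at 4-fold. In that simulation 10.2% of the calls were false, which is above the share that an adjusted p threshold of 0.05 aims at. The share was 17.5% for DESeq2 and 10.8% for limma-voom, so genes called by DESeq2 alone rest on a test with more false calls there. These shares come from a single simulated table with dispersions from the edgeR fit. Their spread over repeated draws was not measured, so the order of the tests may differ in another draw.

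Gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. There were 33 lists with at least 3 measured members, and adjusted p-values were taken over these lists. The erythroid and skeletal muscle lists had 0 measured members. The genes named were also set by a rule fixed before the data were examined. It took Rras2, Rras and Mras, then the 12 largest rises and 12 largest falls among called genes whose groups did not overlap. These needed a mean of at least 5 CPM and a symbol other than a predicted gene model. It then took up to 4 called members of each list by smallest p, or, where none was called, up to 2 of the largest mean. Genes outside the rule are said to be so where they are named, or stand among the tests chosen after the results were seen, and some genes the rule takes are not reported here.

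The alternatives covered other scaling, filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out and mitochondrial and Y-linked genes removed. For DESeq2 and limma-voom the lists were tested with cameraPR, which takes the statistic of each gene. A test against a 1.2-fold change and an estimated list correlation were also run. Restriction to protein-coding genes was planned where the table gave gene types. It gave none, so GENCODE gene types were used and that alternative counts as chosen after the data were examined. Alternatives planned for tables without counts did not apply. Figures were drawn with matplotlib 3.10.9.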

Results

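RNA was sequenced from primary bone marrow stromal cells of 8-week-old mice after 2 days under osteogenic induction. The design compared 3 cKO libraries, from mice with a conditional deletion of Rras2, with 3 FF libraries, from floxed controls. Rras2 encodes TC21, a small GTPase of the R-Ras subfamily. The counts over the 12830 listed genes summed to between 31934714 and 37561452 per library. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise.

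Rras2 was lower in every cKO library than in every FF library. It had 48.2 ± 3.003 CPM in FF (SD, n = 3) and 27.5 ± 1.31 CPM in cKO (SD, n = 3). The log2 fold change was -0.81 with a standard error of 0.0683, which is 1.75-fold lower (edgeR quasi-likelihood test, adjusted p = 1.08e-05). The gene, ENSMUSG00000055723, lies on chromosome 7 from 114046782 to 114117781 on the minus strand of mm10. Its transcripts in cKO were at 0.570 of the FF level. Counts per gene do not show which exons the remaining reads cover or which cells they came from. The related GTPases Rras and Mras had log2 fold changes of 0.15 and 0.01 and did not pass the test (edgeR adjusted p = 0.153 and 0.961).

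**Figure D1:**
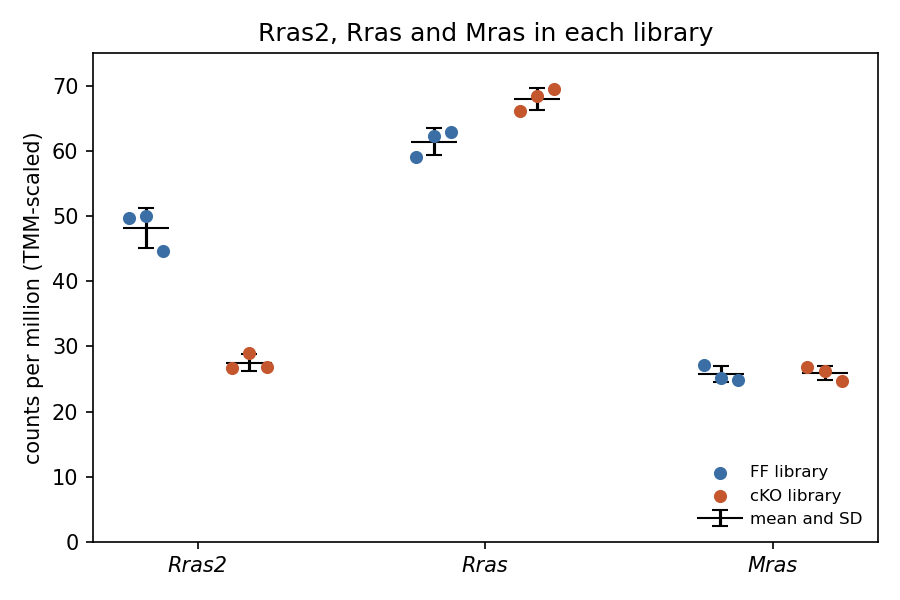
TMM-scaled CPM of Rras2, Rras and Mras in each FF and cKO library, with group means and SDs as bars. The 3 cKO libraries lie between 26.7 and 29.0 CPM for Rras2, and the FF libraries between 44.7 and 50.1 CPM.

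Across the transcriptome the changes were many and mostly small. In cKO, 621 of 12830 genes differed from FF, 270 higher and 351 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The median size of these changes was 1.28-fold. At least 2-fold changes numbered 59, of which 25 were higher and 34 lower. Immunoglobulin genes made up 23 of the 59, with 16 higher and 7 lower. Groups did not overlap for 22.5% of all genes, where chance gives 10%. The authors' deposited table gave 848 genes with an adjusted p below 0.05, and these included all 621. Each library moved the count when left out. It was 371, 268 and 379 without FF replicates 1, 2 and 3, and 1166, 325 and 341 without cKO replicates 1, 2 and 3.

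The 12 falls named here are the largest among called genes with a mean of at least 5 CPM and no predicted-model symbol. That leaves out some immunoglobulin segments of lower mean that fell further. Of 34 genes at least 2-fold lower only 7 were immunoglobulin genes, so genes of other kinds were left out too. Phospho1, a phosphatase that starts matrix mineralisation, was 77.0 ± 5.68 CPM in FF and 31.1 ± 6.08 CPM in cKO (SD, n = 3), a log2 fold change of -1.31. Cthrc1, a secreted collagen-repeat protein, fell by 1.23 on the log2 scale with a standard error of 0.0735 (edgeR adjusted p = 4.86e-07). Nog, a secreted BMP antagonist, fell by 1.47, and Ptgs2, the inducible cyclooxygenase, fell by 1.53. Syt6, Slc36a2, Draxin, Adam12, Gdf10, Creb3l1, Epha2 and Wdfy1 had log2 fold changes between -1.53 and -1.01. Creb3l1 is a transcription factor of collagen secretion. Several of these calls ended when 1 library was left out. Phospho1 had an adjusted p of 0.0768 without FF replicate 2 and 0.0720 without cKO replicate 2. Without cKO replicate 2, Slc36a2 had 0.0504 and Adam12 had 0.0775. Draxin had 0.0523 without cKO replicate 3, and Epha2 had 0.0509 without FF replicate 1. Gdf10 had 0.0597, 0.125 and 0.0885 without FF replicates 1, 2 and 3, and 0.162 and 0.0996 without cKO replicates 2 and 3. Creb3l1 had 0.140, 0.130 and 0.0969 without FF replicates 1, 2 and 3, and 0.157 without cKO replicate 2.

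Antibody genes led the 12 rises named here, which needed a mean of at least 5 CPM as the falls did. The heavy-chain constant genes Ighg1 and Igha had log2 fold changes of 1.39 and 1.04, and Jchain, which joins secreted IgA and IgM, had 0.99. Igkv8-19, a light-chain variable segment, had 0.247 ± 0.201 CPM in FF and 14.0 ± 1.56 CPM in cKO (SD, n = 3). Variable segments resemble one another, so reads shared among them make their single values uncertain. Outside the antibody genes, Adipoq, the adiponectin gene, was 1.93-fold higher (edgeR adjusted p = 4.56e-05), and Bmp6, a bone morphogenetic protein, was 1.75-fold higher. Abi3bp, a matrix-associated protein gene, went from 53.8 ± 5.21 to 94.95 ± 6.36 CPM (SD, n = 3). Otor, Mpp7 and Negr1 had log2 fold changes of 0.98, 0.95 and 0.92. Sfrp4, a secreted Wnt inhibitor, had 1.04, with an adjusted p of 0.0197 that became 0.0612, 0.0915 and 0.0671 without FF replicate 2, FF replicate 3 and cKO replicate 2, and 0.172 with the replicate number as a block. Prnd had 0.87 and lost its call without FF replicate 1 or 3 and without cKO replicate 1, 2 or 3 (adjusted p = 0.0739, 0.133, 0.0611, 0.130 and 0.0558).

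**Figure D2:**
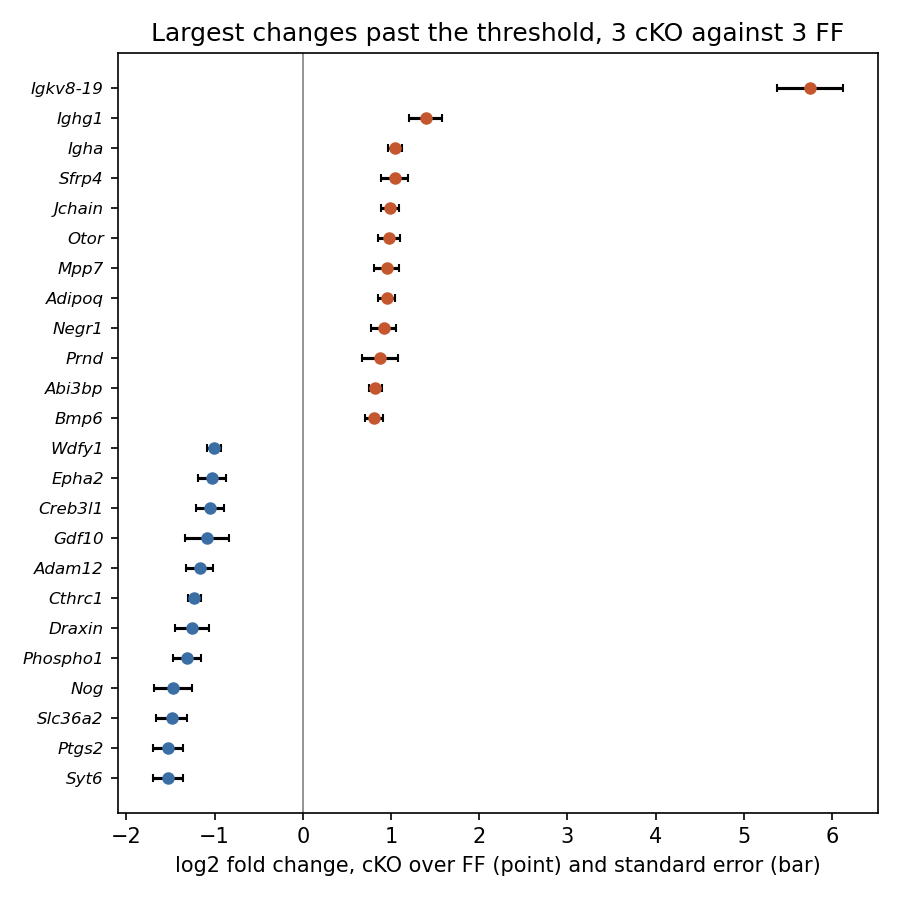
Log2 fold changes of cKO over FF (points) with standard errors (bars) for the 12 largest rises and 12 largest falls chosen by the fixed rule. Among those drawn, Igkv8-19 is at 5.75, the other rises lie between 0.81 and 1.39, and the falls between -1.53 and -1.01. Variable segments below a mean of 5 CPM are not drawn. Of those called, Igkv19-93 and Ighv1-53 had 3.75 and 3.64, and Ighv1-15, with 0 counts in each FF library, had 8.6.

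Camera called the osteoblast list lower at the preset correlation (adjusted p = 6.66e-11) but not with an estimated correlation (adjusted p = 0.372), and its fry adjusted p was 0.0446. The mean log2 fold change of the list was -0.50. Of 20 measured members 6 fell and 0 rose, and adjusted over the list alone 15 fell and 2 rose. Col1a1 and Col1a2, the chains of type I collagen, fell by 0.59 and 0.44 on the log2 scale, and Sparc, the osteonectin gene, fell by 0.34. Runx2, Alpl and Sp7 lie outside the naming rule and were chosen after their values were seen. Runx2, the master regulator of the lineage, fell by 0.25 (edgeR adjusted p = 0.0128). Its adjusted p was 0.0740, 0.0538 and 0.0632 without FF replicate 3, cKO replicate 2 and cKO replicate 3. Alpl, the tissue alkaline phosphatase, had 1561 ± 36.1 CPM in FF and 989 ± 195 CPM in cKO and did not pass the test (edgeR adjusted p = 0.117). DESeq2 called Alpl with all 6 libraries (adjusted p = 0.00217), and edgeR did without cKO replicate 1 or cKO replicate 3 (4.95e-07 and 0.0279). Sp7 had a log2 fold change of -0.70 and an edgeR adjusted p of 0.158. It passed in DESeq2 (0.00482) and without cKO replicate 1 (0.000622).

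Camera also called the matrix and BMP output lists lower at the preset correlation (adjusted p = 7.47e-10 for both), but not with an estimated correlation (adjusted p = 0.372 and 0.365). In the extracellular matrix list 11 of 23 members fell and 1 rose, and adjusted over the list alone 15 fell and 2 rose. Col12a1, a collagen of fibril surfaces, went from 1491 ± 12.9 to 1037 ± 32.4 CPM (SD, n = 3). Postn, Dcn and Fmod fell by 0.50, 0.47 and 0.97 on the log2 scale. The fry adjusted p of the list was 0.0303. In the BMP and TGFb output list 7 of 14 members fell and 0 rose, and adjusted over the list alone 9 fell. Id3, an inhibitor of differentiation induced by BMP signals, went from 192 ± 4.01 to 112 ± 8.26 CPM (SD, n = 3; edgeR adjusted p = 1.14e-06). Id1 and Bambi fell by 0.85 and 0.73. This list had a fry adjusted p of 0.0159.

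Marrow stroma genes are those of the niche cells that support blood formation. Camera called their list higher at the preset correlation (adjusted p = 0.00195) but not with an estimated correlation (adjusted p = 0.365). The estimated correlation was -0.0144, below the preset 0.01, so a higher correlation among members does not account for the lost call. Of 19 members 9 rose and 0 fell, and adjusted over the list alone 9 rose and 1 fell. Cxcl12, the chemokine that retains blood stem cells, went from 3483 ± 98.8 to 4838 ± 178 CPM (SD, n = 3; edgeR adjusted p = 9.98e-05). Lepr, the leptin receptor, Grem1, a BMP antagonist, and Ebf3, a transcription factor of these cells, had log2 fold changes of 0.47, 0.43 and 0.39. The list had a fry adjusted p of 0.00665. Adipocyte genes were mixed. Of 13 members 2 rose and 2 fell, both over all genes and adjusted over the list alone. Adipoq and Cd36, a fatty acid transporter, were higher by 0.95 and 0.39, and Scd1, a fatty acid desaturase, fell by 0.30. Fasn fell by 0.28, a call that ended without FF replicate 1 or 2 and without cKO replicate 2 or 3 (adjusted p = 0.0895, 0.123, 0.131 and 0.0845). Camera did not call the adipocyte list (adjusted p = 0.295).

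Chondrocyte genes had 0 calls among the 7 members measured of 13, and 2 fell adjusted over the list alone. Col2a1 and Comp had log2 fold changes of -0.22 and -1.07. That list's camera adjusted p was 0.0230, and 0.0530 and 0.0518 without FF replicate 2 and cKO replicate 2. With an estimated correlation it had an adjusted p = 0.523. Comp did not pass the main gene test (edgeR adjusted p = 0.102). It passed in DESeq2, in limma-voom and with the replicate block (0.00144, 0.0422 and 8.71e-05), and without cKO replicate 1 (6.78e-06). Col2a1 did not pass either (edgeR adjusted p = 0.309), but did in DESeq2 (0.0460) and without FF replicate 1 (0.0237). Matrix proteases and their inhibitors were not called as a list (camera adjusted p = 0.0770, and 0.0441 without FF replicate 2). Of 14 members 1 rose and 3 fell, and adjusted over the list alone 2 rose and 5 fell. Timp3, a protease inhibitor, was higher by 0.30, and Adamts1, a protease, fell by 0.35. Timp1 fell by 0.28 and lost its call without FF replicate 1 or 2 or cKO replicate 2 (adjusted p = 0.0641, 0.0618 and 0.0530), and with the replicate block (0.0918). Mmp2 fell by 0.18, and lost its call without FF replicate 1, 2 or 3 and without cKO replicate 2 or 3 (adjusted p = 0.171, 0.185, 0.0781, 0.0945 and 0.218).

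Over all tested genes 4.84% were called, a share to set beside the lists below. In the ERK output list, which holds feedback regulators and early targets of ERK, 1 of 19 members rose and 1 fell, the counts being equal adjusted over the list alone. Spry1, a feedback inhibitor, had a log2 fold change of 0.48 (edgeR adjusted p = 0.00348), and Epha2, a receptor tyrosine kinase, fell by 1.03, with adjusted p = 0.0509 without FF replicate 1. Camera did not call that list (adjusted p = 0.704). Its median log2 fold change was 0.037 and its mean -0.0085. In the FOXO output list 1 of 13 members, Klf15, rose, by 0.71, and the count adjusted over the list alone was also 1. Klf15 lost its call without FF replicate 1, 2 or 3 and without cKO replicate 2 or 3 (adjusted p = 0.119, 0.0882, 0.0604, 0.0829 and 0.154). The FOXO list had a camera adjusted p of 0.0325, which was 0.193, 0.0566 and 0.0622 without FF replicates 1 and 2 and cKO replicate 2. From DESeq2 and limma-voom gene statistics it was 0.0679 and 0.0731, and with an estimated correlation 0.523. The other Ras family members had 0 calls of 17 (camera adjusted p = 0.184). In the Wnt output list 1 of 10 fell, Ccn4, by 0.45 (camera adjusted p = 0.452, mean -0.15 and median 0.0023). YAP output genes had 0 calls of 13 and integrin and focal adhesion genes 0 of 20 (camera adjusted p = 0.748 and 0.708). Contractile genes had 1 of 12, Tpm1, higher by 0.20 (camera adjusted p = 0.175). Tpm1 lost its call without FF replicate 1, 2 or 3 and without cKO replicate 2 or 3 (adjusted p = 0.203, 0.118, 0.111, 0.210 and 0.119), and with upper-quartile scaling or library totals alone (0.0528 and 0.0586).

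**Figure D3:**
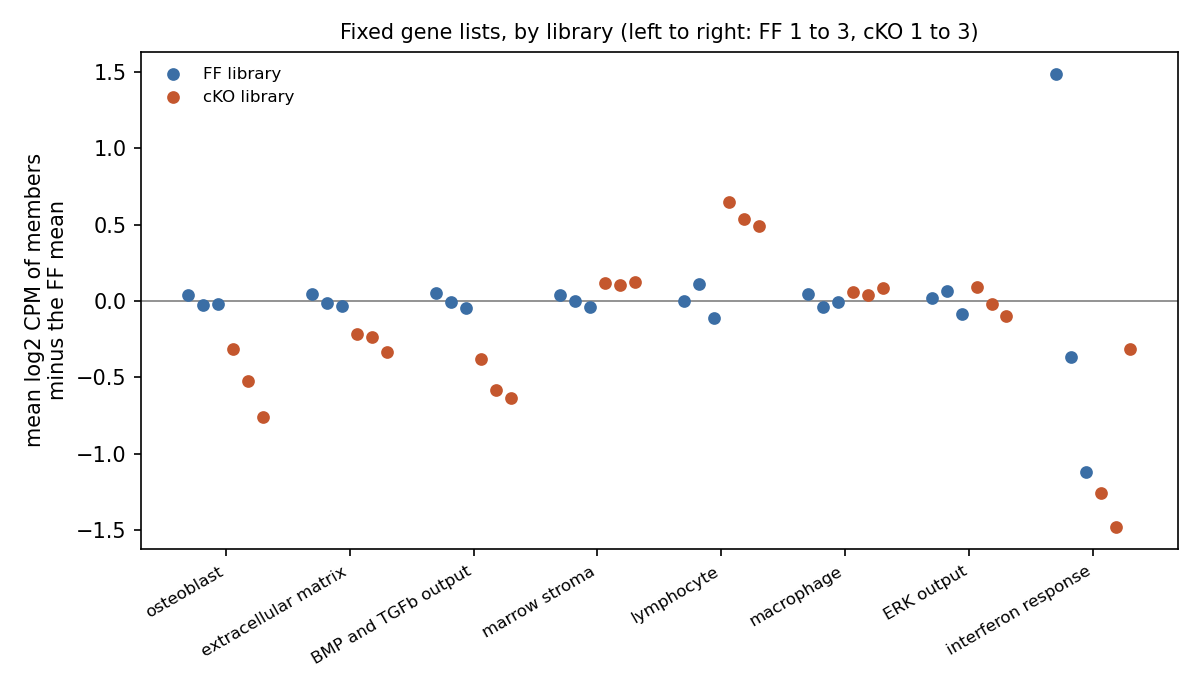
Mean log2 CPM of each list's members minus the FF mean, with 1 point for each FF and cKO library. The 3 cKO libraries lie at -0.32 to -0.76 for osteoblast genes and at 0.10 to 0.13 for marrow stroma genes, and FF replicate 1 stands at 1.48 for interferon response genes.

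Transcripts of blood cells were present in the cultures. In the lymphocyte list 3 of 10 members were measured and 2 of them, both immunoglobulin constant genes, rose, also when adjusted over the list alone (camera adjusted p = 0.000202; adjusted p = 0.372 with an estimated correlation). Igkc, the kappa light-chain constant gene, went from 55.5 ± 1.99 to 95.1 ± 1.27 CPM (SD, n = 3; edgeR adjusted p = 7.39e-07). Ighm had a log2 fold change of 0.73. It lost its call without any 1 FF replicate (adjusted p = 0.0626, 0.10 and 0.0757 for replicates 1, 2 and 3) and without cKO replicate 2 (0.0883). Of 15 macrophage genes 2 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell. Tyrobp and Mrc1 had log2 fold changes of 0.26 and 0.18, and Cd14 fell by 0.18. Tyrobp lost its call without FF replicate 2 and cKO replicates 2 and 3 (adjusted p = 0.0976, 0.0615 and 0.0568). Cd14 lost its call without any 1 FF replicate (0.0778, 0.0704 and 0.0924) and without cKO replicate 2 (0.0784). The call of Mrc1 ended without any 1 FF replicate (0.208, 0.114 and 0.105), without cKO replicate 2 or 3 (0.178 and 0.133), and with upper-quartile scaling or library totals alone (0.0537 and 0.0606). The macrophage list had a camera adjusted p of 0.0385, which was 0.230, 0.0814, 0.0863 and 0.101 without FF replicates 2 and 3 and cKO replicates 1 and 3. With an estimated correlation its adjusted p = 0.523. Osteoclast genes had 1 call of 10, Atp6v0d2, a proton pump subunit, higher by 0.47. The osteoclast list had a camera adjusted p of 0.00998, which was 0.0530, 0.0557 and 0.135 without FF replicates 2 and 3 and cKO replicate 1 (adjusted p = 0.523 with an estimated correlation).

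Neutrophil genes had 0 calls of 7 (camera adjusted p = 0.0325; adjusted p = 0.523 with an estimated correlation). That call ended without FF replicate 2, cKO replicate 1 or cKO replicate 3 (adjusted p = 0.243, 0.222 and 0.136), and with DESeq2 and limma-voom gene statistics (0.0679 and 0.12). Megakaryocyte and mast cell genes had 0 calls among the 4 members measured of 7, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.748, mean -0.033 and median 0.063). Pf4, a platelet chemokine gene, had a log2 fold change of 0.28 and an edgeR adjusted p of 0.177. It passed in DESeq2 and with the replicate block (0.0116 and 0.00791), and without cKO replicate 1 (0.000210). Endothelial genes had 0 calls of 8 (camera adjusted p = 0.0885, 0.0323 with the replicate block and 0.00802 without FF replicate 3). Osteoclast support genes had 0 calls of 6, and 2 rose adjusted over the list alone (camera adjusted p = 0.175). Tnfrsf11b, the osteoprotegerin gene, had a log2 fold change of 0.47 and passed without cKO replicate 1 (adjusted p = 0.000164). Sex-linked genes had 1 call of 4, Eif2s3y, higher by 0.24 (camera adjusted p = 0.175). That call ended without FF replicate 1, 2 or 3 and without cKO replicate 2 or 3 (adjusted p = 0.0526, 0.0908, 0.0671, 0.0687 and 0.0521).

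Interferon response genes separated libraries more than groups. All 16 members had negative log2 fold changes, 0 passed, and 0 passed adjusted over the list alone. Camera called the list (adjusted p = 0.000534), but with an estimated correlation its adjusted p = 0.523. FF replicate 1 carried the difference. Ifit3, an interferon-induced gene chosen after its values were seen, had 238 CPM there, 38.8 and 17.8 CPM in the other FF libraries, and 16.7, 12.2 and 37.4 CPM in cKO. Without FF replicate 1 the mean log2 fold change of the list went from -1.37 to -0.22 (camera adjusted p = 0.104). The call also ended with limma-voom gene statistics (0.0840). In the inflammatory secretion list 1 of 11 fell, Ptgs2 (camera adjusted p = 0.175, and 0.0465 without FF replicate 3).

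In the ER and amino acid stress list 3 of 12 fell, and 4 adjusted over the list alone (camera adjusted p = 0.0503). It passed without FF replicate 3, cKO replicate 2 or cKO replicate 3 (adjusted p = 0.0131, 0.0428 and 0.0280). With all 6 libraries it passed with DESeq2 and limma-voom gene statistics and without mitochondrial and Y-linked genes (0.0474, 0.0401 and 0.0475), and narrowly with RLE scaling (0.05 after rounding). With an estimated correlation its adjusted p = 0.523. Asns, asparagine synthetase, fell by 0.34. Chac1 and Trib3 fell by 0.65 and 0.50. Chac1 lost its call without FF replicates 2 and 3 and cKO replicate 3 (adjusted p = 0.105, 0.0765 and 0.0699). Trib3 lost its call without FF replicates 1 and 2 and cKO replicates 2 and 3 (adjusted p = 0.0902, 0.129, 0.0666 and 0.0862). In the cell cycle list 20 of 21 members had negative log2 fold changes and 1 fell, Mcm5, by 0.22, and 2 fell adjusted over the list alone. Camera called the list (adjusted p = 0.000437), but with an estimated correlation its adjusted p = 0.484. Mcm5 lost its call without FF replicates 1 and 2 and cKO replicates 2 and 3 (adjusted p = 0.0614, 0.263, 0.0951 and 0.179). Cholesterol synthesis genes had 0 calls of 14, and 6 fell adjusted over the list alone (camera adjusted p = 0.00192, and 0.0578 without FF replicate 1; adjusted p = 0.523 with an estimated correlation). Srebf2 had a log2 fold change of -0.16 and passed without cKO replicate 1 (adjusted p = 0.00172). Respiratory chain genes had 0 calls of 17 (camera adjusted p = 0.00998, and 0.0566 without FF replicate 2; adjusted p = 0.523 with an estimated correlation).

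Vegfa, a vessel growth factor, fell by 0.54 on the log2 scale and was the 1 call among 15 hypoxia and glycolysis genes, where 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.150, and 0.0455 without FF replicate 3). In the p53 output list 1 of 12 rose, Plk2, by 0.24, and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.748). Plk2 lost its call whichever library was left out, with adjusted p from 0.0566 to 0.168, and with the replicate block (0.0557). Senescence-related, immediate early and mitochondrial transcript lists had 0 calls of 5, 11 and 9 (camera adjusted p = 0.168, 0.748 and 0.452). Junb had a log2 fold change of -0.22 and passed without cKO replicate 1 (adjusted p = 0.00927). The immediate early list had a mean of 0.0040 and a median of -0.018.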

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

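Alternatives were chosen before the data were examined, except the restriction to protein-coding genes by GENCODE type. Rras2 kept its direction and its call in all 16 alternatives run for it, with log2 fold changes from -0.86 to -0.78. The 621 changed genes became 602 to 669 under other scaling, limma-voom, the replicate block or without mitochondrial and Y-linked genes, and 848 with DESeq2, which called all 621. Both other filters removed 0 genes and so tested nothing. A test against a 1.2-fold change called 101 genes, since it asks for a larger change. Leaving out 1 library gave 268 to 1166 changed genes, 107 to 535 higher, 161 to 631 lower and 40 to 103 changed at least 2-fold. The highest count of each came without cKO replicate 1, and the cause was not tested. Pairs of libraries were compared by the chi-square of each gene, its median divided by that of sampling noise. For cKO replicate 1 this was 6.57, 6.48 and 5.63 against FF replicates 1, 2 and 3. Against cKO replicates 2 and 3 it was 6.88 and 6.86. The mean chi-square instead put cKO replicate 2 nearest to it (13.7), then FF replicate 3 (16.1). Restricting to 12539 protein-coding genes gave 35 genes at least 2-fold changed, 34 of them among the 59 of the main fit. Immunoglobulin genes, which made up 23 of the 59, were then not tested. Camera called 14 lists, 9 to 16 with 1 library left out and 0 with an estimated correlation. With that correlation 3 lists had an unadjusted p below 0.05. Since 0 lists passed there, a call lost in that setting does not by itself show that it rested on correlated members. The marrow stroma list lost its call although its estimated correlation, -0.0144, was below the preset 0.01. Fry called 5 lists, the osteoblast, extracellular matrix, BMP and TGFb output, marrow stroma and lymphocyte lists (adjusted p = 0.00694 for the last). It did not call the other lists that camera called (fry adjusted p = 0.0891 to 0.44). The 93 other named genes gave 1480 values under alternatives, of which 1376 stayed on their side of the threshold, 90 lost a call, 14 gained one and 0 reversed. The 1376 include the values under both filters that removed 0 genes, which could not change. Of 63 called named genes, 40 were called in all their alternatives. The replicate block gave 669 genes, 562 of them shared with the 621. The numbers were not taken to pair the samples, since deviations of same-numbered libraries correlated at -0.036, 0.091 and -0.099. Genes with a mean below 22.3 counts were not analysed here.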

Other observations

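All tests in this part, and the genes named in it, were chosen after the results were seen, except the counts over other splits of the libraries, which every group comparison was given. Their written predictions also came after the results. Of 6 further gene lists, written after called genes had been seen, 3 or more members of each were called, so these counts are not independent evidence. Collagen processing genes had 10 of 23 members lower and 1 higher, among them Serpinh1, a collagen chaperone, and Fkbp10, a collagen-folding isomerase, which fell by 0.26 and 0.36 on the log2 scale. Serine, glycine and proline synthesis genes had 6 of 14 lower and 0 higher, with Aldh18a1, a proline synthesis enzyme, down by 0.32 and Aldh1l2 by 0.75. Genes of COPII transport and ER translocation had 7 of 31 lower, and cytosolic aminoacyl-tRNA synthetases had 3 of 20 lower. Vacuolar ATPase subunits had 5 of 17 higher and 0 lower. Camera gave these 5 lists adjusted p-values from 6.52e-11 to 0.000437, but with an estimated correlation none was called (adjusted p = 0.266 to 0.312, unadjusted p = 0.0281 to 0.0844). Their fry adjusted p-values ran from 0.0152 to 0.0677, the highest being that of COPII transport and ER translocation. Fry too was run on lists written after called genes had been seen.

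BMP ligands and their antagonists went both ways, with 6 of 17 measured members higher and 4 lower (camera adjusted p = 0.0788, fry adjusted p = 0.0411). Bmp4 and Bmp6 had log2 fold changes of 0.47 and 0.81, and the antagonists Grem1 and Chrdl1 had 0.43 and 0.46, while the antagonist Nog fell by 1.47. Terms of the authors' deposited annotation were tested for enrichment among called genes with a hypergeometric test, which treats genes as independent although expression is correlated between genes. Of 13307 terms tested in each direction, 183 passed among the higher genes and 654 among the lower ones (adjusted p below 0.05). The 3 terms of smallest p are given here. Immunoglobulin complex took 19 of 44 annotated genes among the higher ones, where 0.919 were expected (adjusted p = 1.48e-16). Among the lower ones, cellular response to BMP stimulus took 30 of 181, where 5.01 were expected (adjusted p = 1.77e-11), and extracellular matrix binding took 34 of 224, where 6.21 were expected (adjusted p = 5.21e-12). Insc, 626 kb from Rras2 on chromosome 7, fell by 0.86, and Mical2 fell by 0.25 (adjusted p = 0.0614 without FF replicate 2). These were the 2 called genes among 15 measured within 2 Mb of Rras2, beside 4.84% called over all tested genes. Mical2 lies 1630 kb from Rras2, and Spon1, the nearest at 3.41 kb, was not called (edgeR adjusted p = 0.533). An effect of the locus on its neighbours was not tested.

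The 10 splits of the 6 libraries into 3 and 3 are too few for a share below 0.05. The real split was the 1 with the most changed genes, 621 against at most 3 in the others, and with the most genes changed at least 2-fold, 59 against at most 3. Its larger direction held 351 genes, against at most 2. It also had the most lists called by camera, 14, but another split gave 13, so the number of lists called with the preset correlation barely set the real groups apart.

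Of 33 immunoglobulin variable genes, 15 were called higher, 5 lower and 13 not called. In some of those called the libraries of a group had similar counts. Ighv1-53 had 20, 32 and 14 counts in FF and 279, 277 and 279 in cKO, and Igkv8-27 had 213, 238 and 187 in FF and 11, 14 and 20 in cKO. A larger number of antibody-producing cells of one makeup would raise all variable genes, but 5 of the 20 called were lower. The between-group chi-square of the 33 variable genes had a median 30.2 times that of the within-group chi-square per degree of freedom. For 2332 other genes of like count it was 0.963 times. The within-group chi-square has more degrees of freedom, so these medians differ even without a group difference. The 0.963 therefore does not show that other genes had none. The ratio of the variable genes restates the difference on the genes in which it was seen. It does not test whether the 3 libraries of a group came from a single pool of marrow cells. That and germline differences between the groups cannot be told apart here, since the labels name no animals and no genotypes were analysed for the 9 called variable genes on chromosome 6 and 11 on chromosome 12.

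In the osteoblast, matrix and BMP output lists 6 of 20, 11 of 23 and 7 of 14 members were called lower, and in the marrow stroma list 9 of 19 were called higher. With an estimated correlation camera called none of these lists (adjusted p = 0.372, 0.372, 0.365 and 0.365). It called 0 of the 33 fixed lists in that setting, so the loss does not single these lists out. Dilution of all stromal RNA by more macrophages would lower stroma genes too, but 9 marrow stroma genes were called higher and 0 lower. Of the 19 members 12 had positive and 7 negative log2 fold changes, and 1 fell adjusted over the list alone. These genes are part of the pattern to be explained, so their count is no separate test of dilution. The interferon state of FF replicate 1 does not account for the lower osteoblast list, which kept a mean log2 fold change of -0.483 without that library. A difference between 2 cell pools other than Rras2 cannot be told apart from the genotype, because the labels do not say whether the libraries of a group came from separate animals. The spread of variable genes within groups does not settle it (median chi-square per degree of freedom 2.57, against 2.93 for other genes of like count). An effect of Rras2 loss therefore stays open as a hypothesis.

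Interferon response genes were lower in cKO on average. A candidate explanation is 1 FF library in a high interferon state, and without FF replicate 1 the mean log2 fold change was -0.222 in place of -1.37. No biological explanation was tested for that state.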
